A study of Homo sapiens with 18 samples.

How the data were processed

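SuRE (survey of regulatory elements) tests random pieces of a genome for promoter activity outside their chromosomal setting. In the study, fragments of human genomic DNA were cloned in front of a random barcode in a plasmid without a promoter, and the plasmids were transfected into K562, an established human erythroleukaemia line. A barcode is transcribed when its fragment acts as a promoter toward it. Per the labels' protocols, cells were transfected by nucleofection and harvested after 24 hours, and barcodes in polyadenylated RNA were copied with a reporter-specific primer, amplified and sequenced. Inverse PCR (iPCR) of the plasmid pool linked each barcode to its fragment, and barcodes in plasmid DNA gave the input.

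The 18 samples comprised 1 fragment map, 2 plasmid PCR replicates and 6 cDNA PCR replicates of a genome-wide library, and 1 fragment map, 2 plasmid, 2 untreated cDNA, 2 solvent cDNA and 2 hemin cDNA samples of a smaller library made from bacterial artificial chromosomes (BACs). Per the labels, the genome-wide cDNA came from 2 transfections with 4 and 2 PCR replicates, the untreated BAC cDNA from 2 transfections, and the hemin and solvent arms each from 1 transfection with 2 PCR replicates. The treatment protocol in the labels speaks of 3 biological replicates, of which only the listed ones were used here.

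The values in both fragment tables were deposited as raw read counts per fragment and barcode, with no normalisation. Per the submitters' processing notes, the genome build was hg19 and the tools were cutadapt and Bowtie2, without a role or order for either, and per the labels' extract protocol cutadapt 1.2.1 removed the adapter before barcodes were counted. The transcription start site (TSS) table was deposited with 1 activity signal per TSS that pools both transfections, on a scale that the authors did not state. Its TSS positions, strands and gene symbols were used for all comparisons, and its signal was used only for a comparison with the activities computed here. It listed 28844 TSSs of 15568 gene symbols. In the BAC table, 4 plasmid columns were not matched to the 2 plasmid samples and were not used here, so BAC activities were expressed per mapped fragment.

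For each TSS, reads were summed over the fragments that contained the TSS base, separately for fragments in the orientation of the gene (sense) and the opposite orientation (antisense). Activity is the share of a library's cDNA reads divided by the share of plasmid reads. Activity per fragment is the share of cDNA reads divided by the share of mapped fragments, so that the library mean is 1. Errors are standard deviations over 2 transfections unless stated otherwise. PCR replicates of a transfection were summed, because they are not separate transfections.

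Active TSSs were called with edgeR's quasi-likelihood F-test (glmQLFit with robust estimation and glmQLFTest), cDNA of 2 transfections against 2 plasmid libraries, with Benjamini-Hochberg adjusted p under 0.05 and cDNA above plasmid. Per the labels the 2 plasmid libraries are PCR replicates, so their part of the spread is technical. Library sizes were the totals of the fragment table with no further factor, because most TSSs may differ from the rest of the genome. A TSS was tested with at least 10 fragments and 10 reads over all libraries, which 21848 TSSs met and 6996 did not. The sense against antisense test was the interaction of library type and orientation in the same kind of fit. For gene lists, 1 TSS per gene was kept, the one with the most plasmid reads, and the share of active genes in each of 23 lists was compared with all other tested genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. The median activity of a list was placed among 10000 random lists matched on plasmid reads, with a pseudocount of 1 read.

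The BAC library was counted at a grid of points each 500 bp, strands apart, and at each TSS. The tested points were those that passed edgeR's filterByExpr. The fit used TMM factors and 3 groups (untreated, solvent, hemin), so the spread came from the 2 untreated libraries alone, and each single arm was assumed to vary like them. Grid points and TSSs were scaled separately. The BAC and genome-wide libraries were compared by log2 activity per fragment at positions with at least 10 fragments in both.

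Named genes followed a rule. For activity they were the 12 genes with the highest fitted fold, and for orientation the 6 most biased genes in each direction, each with at least 10 fragments, the same direction in both transfections, no fragment with over 50% of the cDNA reads and no second gene with a TSS within 100 bp. For each list they were its most active, median and least active member by activity over plasmid, and every globin gene with a listed TSS. For hemin they were the 6 largest rises and 6 largest falls with at least 50 reads over both arms. The separate hemin results of 1 BAC region and of its genes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. The comparisons, tests, lists and naming rule were set before the data were examined.

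Folds of genes without plasmid reads are lower bounds against a floor of 3 reads over both plasmid libraries. These bounds do not allow for the choice of the genes by their fold. Floors and intervals cover counting error only, since reads were amplified by PCR and carry no molecular identifiers.

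The tests were tested on simulated data with 100 changed features per fold size. Changed features were drawn only from those with at least the median number of reads. Before the change, each feature had the same share in every library. Simulated plasmid counts at changed TSSs were therefore above the real median of 4 reads, and recovery at typical TSSs was not measured. Every library had the fitted spread, so the assumption on the single hemin and solvent arms was not tested. The activity test over 21848 TSSs recovered 34% of 4-fold and 100% of 16-fold changes with 8 false calls. The orientation test over 21226 TSSs recovered 7% of 4-fold and 77% of 16-fold changes with 4 false calls. The hemin test over 6138 points recovered 100% of 2-fold and 100% of 4-fold changes with 18 false calls. The list test over 11800 genes called 0 of 23 lists with random calls and 1 with 1 planted list, the ribosomal protein genes all set to active.

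Alternatives covered scaling (TMM, DESeq2, table totals), the filter on low counts, mapped fragments as input, leaving out the fragment with the most cDNA reads, fragments reaching at least 200 bp upstream, stricter folds, the grid step, PCR replicates as separate libraries, replicate blocks, pseudocounts and leaving out each replicate. The planned comparison of activity with endogenous transcription was dropped, because the TSS table held no such measure. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.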

Results

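The genome-wide library held 153562178 mapped fragments with a median length of 1004 bp. The 4 PCR replicates of transfection 1 held 9576776, 13208925, 7047940 and 7937012 cDNA reads, and those of transfection 2 held 35494007 and 38587027. Transfection 1 therefore totalled 37770653 reads and transfection 2 totalled 74081034. The plasmid PCR replicates held 24529456 and 25651210 reads. Between 1.16% and 1.42% of fragments had a read in a PCR replicate of transfection 1, against 8.64% and 9.05% in transfection 2. The median tested TSS was covered by 19 sense fragments with 4 plasmid reads and with 34 and 115 cDNA reads in transfections 1 and 2. The BAC library held 781022 fragments with a median length of 257 bp over 9 regions of 1559949 bp in total. Its untreated cDNA libraries held 477025 and 410725 reads, the solvent PCR replicates 2262801 and 1872150, and the hemin PCR replicates 1884686 and 1791281.

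The first comparison asked which annotated TSSs drive transcription on their own, outside the chromosome. RPL8, which encodes a protein of the large ribosomal subunit, had an activity per fragment of 311 ± 158 (SD, n = 2 transfections) at 8:146017808. Its 29 sense fragments had 0 plasmid reads, so cDNA was at least 982-fold above plasmid. RAN, which encodes the GTPase of nuclear transport, reached 331 ± 161 and at least 397-fold, and RBM17, a splicing factor gene, reached 134 ± 30.9 and at least 393-fold. TCEB2, which encodes an elongin subunit, reached 127 ± 43.5 and at least 373-fold. RP9, whose protein is linked to splicing and to inherited retinal disease, reached 113 ± 37.8 and at least 370-fold. SEPT7P9, a septin pseudogene, reached 145 ± 14.2 and at least 331-fold. RNPC3, which encodes a protein of the minor spliceosome, reached 175 ± 43.4 and at least 324-fold. The other promoters named by the rule were KIAA2013 (a membrane protein gene, 138 ± 25.8), USP10 (a deubiquitinase, 115 ± 35.5), H3F3A (a replacement histone, 167 ± 2.13), RNVU1-19 (a variant small nuclear RNA, 208 ± 36.3) and EEF1D (a translation elongation factor subunit, 152 ± 54.9), at least 315-, 312-, 309-, 295- and 281-fold above plasmid.

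Of the 21848 tested TSSs, 15309 (70.1%) were higher in cDNA than in plasmid and 63 (0.288%) were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 1 TSS per gene, 7612 of 11800 genes (64.5%) were active and 43 were lower. The 12 named TSSs owe their rank in part to the absence of plasmid reads, which 996 tested TSSs shared. At all 12 the bound over plasmid exceeded the activity per fragment, for example 982 against 311 at RPL8. The bounds may therefore rest on a low draw of plasmid reads and are not lower bounds on activity. Ranked instead by activity per fragment, a measure chosen after the values were seen, ribosomal protein promoters led, with RPS27 at 433 ± 347, RPS20 at 423 ± 217 and RPL28 at 412 ± 325 (SD, n = 2 transfections). They were followed by SSU72, a phosphatase gene of the transcription machinery, at 395 ± 134 and by H3F3B, a replacement histone gene, at 385 ± 83.7. The number of active TSSs rests on scaling by table totals, under which the median TSS lay at 4.76 on the log2 scale. TMM and DESeq2 factors placed that median at 0.24 and 0.10, and counted 5555 higher against 4775 lower and 4670 higher against 5989 lower TSSs. These counts give activity relative to the typical TSS instead of the genome. The 63 lower TSSs rose to 611 without transfection 1 and to 1067 without transfection 2, where the lone cDNA library was assumed to vary like the plasmid pair.

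Housekeeping gene lists were almost uniformly active. Median activity lay at percentile 100 of the matched random lists for ribosomal protein, respiratory chain and proteasome genes and for ZNF symbols. It lay at 99.95 for tRNA synthetases, and lower, at 94.5 and 93.2, for cell cycle and histone genes. Active promoters were found for 69 of 70 ribosomal protein genes (Fisher's exact test, adjusted p = 3.26e-11), with a median activity per fragment of 159. Members were ranked by activity over plasmid, so their activities per fragment need not follow that order. The median member by that rank, RPS27A, had 330 ± 219 per fragment (SD, n = 2 transfections). The exception was RPL4, whose TSS at 15:66815749 had 0 cDNA reads and 11 plasmid reads over 24 fragments. A TSS was kept for its plasmid reads, so it need not be the main promoter of RPL4 or of any other listed gene. Of 68 respiratory chain genes 66 were active (adjusted p = 8.20e-10), led by ATP5J2 at 117 ± 51.1 with ATP5G1 as the median at 45.6 ± 25.2. The respiratory chain exceptions were COX6A2 (3.42 ± 4.84), the heart and muscle form of a cytochrome oxidase subunit, and COX6B2 (4.74 ± 0.512), a testis form, the latter named after its value was seen. Proteasome promoters were active in 26 of 27 genes (adjusted p = 0.000749), from PSMD7 at 245 ± 85.7 through PSMC2 at 83.1 ± 30.0 to the interferon-inducible PSMB8 at 3.40 ± 2.90. All 14 tRNA synthetase genes (adjusted p = 0.00784) and all 20 cell cycle genes (adjusted p = 0.000821) were active. SARS, IARS and WARS had 127 ± 40.6, 97.7 ± 56.8 and 12.7 ± 12.9, and the cell cycle genes E2F1, BUB1B and CCND3 had 44.0 ± 12.1, 44.8 ± 16.6 and 3.14 ± 0.930, where E2F1 ranked first with 0 plasmid reads. Replication-dependent histone genes were active in 20 of 21 cases (adjusted p = 0.00540), from HIST2H3A at 56.4 ± 9.65 through HIST1H2AE at 18.5 ± 4.94 to HIST1H1D at 1.89 ± 0.945. Of 361 genes with ZNF symbols, most of them zinc finger transcription factors, 334 were active (adjusted p = 4.11e-35), with ZNF598 at 120 ± 63.5, ZNF512 at 32.1 and 64.7 in transfections 1 and 2 and ZNF474 at 0.167 ± 0.0808.

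Epidermal, liver and lymphoid lists had fewer active promoters than other genes. Their median activities lay at percentiles 0.5, 0.03 and 1.26 of the matched random lists. No epidermal gene of 9 was active (adjusted p = 0.000511, Fisher's exact test), and edgeR gave 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, as did DESeq2 on its own scale. SBSN, DSG3 and TGM3 had activities per fragment of 1.13 ± 0.0907, 1.92 ± 2.72 and 0.0560 ± 0.0792 (SD, n = 2 transfections), where the library mean is 1. DSG3 had 0 and 39 cDNA reads in transfections 1 and 2. Only FGB, a fibrinogen gene named after its value was seen, was active among 10 liver genes (exact test, adjusted p = 0.00199), at 10.7 ± 14.8, a call that ended without the fragment with the most cDNA reads. F9, APOA2 and AHSG of that list had 4.93 ± 2.49 (2.07 without that fragment), 0.259 ± 0.366 and 0.0855 ± 0.00118, the last from 3 reads. Of 12 lymphoid genes only CD3D (6.82 ± 3.90) and IL7R (11.6 ± 6.84, named after its value was seen) were active (exact test, adjusted p = 0.00275), while CD4 had 1.73 ± 2.44 and the B-cell gene MS4A1 had 0.0964 ± 0.136 and was called lower. With mapped fragments as input 0 TSSs were called lower.

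The share of active promoters in the remaining lists did not pass the test against other genes in the main setting. Erythroid transcription factor and membrane genes, which mark the lineage of the line, were active in 9 of 13 cases (Fisher's exact test, adjusted p = 1), from the transferrin receptor gene TFRC at 122 ± 24.0 through ANK1 at 4.32 ± 0.459 to HEMGN at 0.599 ± 0.696 (SD, n = 2 transfections). Haem synthesis genes were active in 5 of 7 cases (exact adjusted p = 1). The housekeeping enzyme gene ALAS1 had 84.8 ± 3.97, UROS had 12.9 ± 3.02 and the erythroid form ALAS2 had 0.734 ± 0.853. The listed TSSs covered only 4 globin genes, HBB, HBD, HBM and HBQ1, so no other globin promoter was measured. Of 3 tested globin genes only HBD was active (exact adjusted p = 0.369), at 10.6 ± 0.656 and, at a second TSS, 7.54 ± 0.706, or 9.45 and 6.65 without the top fragment of each. HBB had 1.47 ± 1.16, or 0.267 without its top fragment, and HBQ1 had 1.55 ± 2.20, and HBM was covered by only 3 fragments and not tested. Haem and oxidative stress genes were active in 8 of 9 cases (exact adjusted p = 0.264), with SRXN1 at 24.4 ± 14.6, NQO1 at 15.9 ± 5.08 and TXNRD1 at 0.594 ± 0.0682. Small nuclear RNA genes were active in 11 of 12 cases (exact adjusted p = 0.129). The median member RNVU1-6 had 87.4 ± 4.71 and RNVU1-17 had 5.38 ± 5.88. The median log2 activity of the list, 7.35, lay at percentile 100 of the matched random lists. With mapped fragments as input this list passed the test (adjusted p = 0.0149).

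Immediate early genes were active in 8 of 11 cases (exact adjusted p = 0.870), with JUND at 220 ± 28.2, IER3 at 26.9 ± 24.8 and MYC, uncalled, at 1.79 ± 0.401 (SD, n = 2 transfections). Heat shock genes were active in 5 of 6 cases (exact adjusted p = 0.524), with HSPA8 at 111 ± 25.4, HSPA1A at 12.2 ± 1.77 and DNAJB1 at 3.66 ± 1.34. Interferon-response genes were active in 10 of 15 cases (exact adjusted p = 1), with STAT2 at 21.0 ± 4.02, DDX58 at 7.05 ± 6.24 and OASL at 0.192 ± 0.271. Cancer-testis genes were active in 7 of 8 cases (exact adjusted p = 0.369), with MAGEC2 at 93.2 and 110.2 in transfections 1 and 2, PAGE1 at 11.9 ± 8.62 and MAGEB1 at 1.17 ± 0.0162. Active genes numbered 2 of 7 among HOX genes (exact adjusted p = 0.173), of which HOXB9 had 9.40 ± 8.91, HOXD12 2.20 ± 3.11 and HOXC4 0.549 ± 0.776, and the second active gene was HOXB7. They numbered 2 of 7 among neuronal genes (exact adjusted p = 0.173), with SNAP25 at 21.1 ± 6.82, STMN2 at 2.61 ± 2.41 and ELAVL4 at 0.861 ± 0.130, and the second active gene was SYT1. Muscle genes were active in 3 of 10 cases (exact adjusted p = 0.0848), with MYL1 at 8.78 ± 5.47, TNNT2 at 0.729 ± 0.119 and TNNI1 at 0.327 ± 0.463, the others being TNNC2 and TTN. Of 3 olfactory receptor genes OR2L13 was active (exact adjusted p = 0.369) at 32.1 ± 6.25, while OR51E2 had 3.98 ± 3.38 and OR7A5 had 0.383 ± 0.280. HOXB7, SYT1, TNNC2 and TTN were named after their values were seen. Single fragments weighed on several of these genes. Without the fragment with the most cDNA reads, activity per fragment was 7.05 at OR2L13, 6.05 at SNAP25, 55.9 at HSPA8, 0.638 at MAGEB1 and 0.489 at ELAVL4, and SNAP25, HOXB7 and TNNC2 were no longer active. Without that fragment the HOX, neuronal and muscle lists passed the exact test as less active than other genes (adjusted p = 0.0452, 0.0244 and 0.0279). They also passed with all TSSs of a gene (0.0442, 0.00340 and 0.000659), where TSSs of 1 gene are not independent. With mapped fragments as input HOX and muscle genes passed (0.00983 and 0.00136). Adjusted over the list alone, the counts of active genes equalled those over all genes except for ZNF symbols (337), HOX genes (1) and liver genes (0). Against the typical TSS, on DESeq2's scale, 62 of 70 ribosomal protein genes, 10 of 12 small nuclear RNA genes and 37 of 68 respiratory chain genes were still higher in cDNA, but only 97 of 361 genes with ZNF symbols, 3 of 21 histone genes and 0 of the 3 globin genes (1 by edgeR at an unadjusted p under 0.05).

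**Figure D1:**
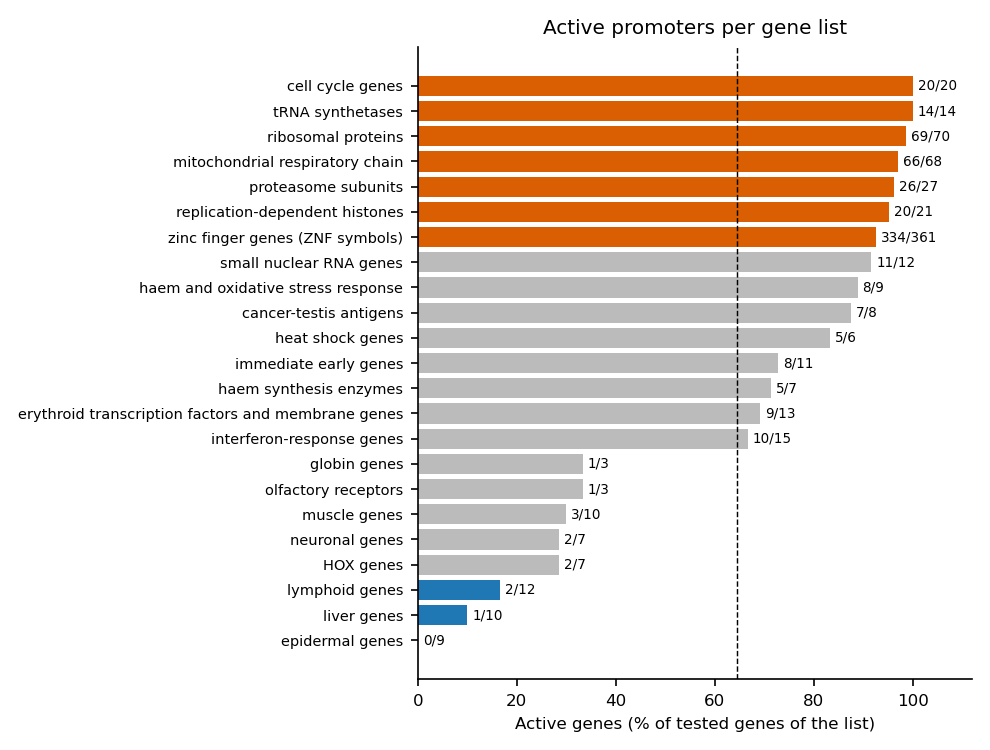
Bars give the percent of tested genes of each list with an active promoter in the genome-wide library, with active and tested genes beside each bar; orange and blue bars differ from all other tested genes by Fisher's exact test after adjustment (higher and lower), and grey bars do not. The dashed line marks 64.5% of all 11800 tested genes, and the lists run from 0 of 9 epidermal genes to 20 of 20 cell cycle genes.

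The second comparison asked whether promoter fragments drive transcription toward the gene or away from it. Sense fragments were more active than antisense fragments at the typical TSS. Median log2 activity over 21226 TSSs was 4.17 for sense and 2.90 for antisense fragments. Sense activity per fragment was higher in both transfections at 12462 TSSs (58.7%), and antisense activity at 3788 (17.8%). Both orientations rose together across TSSs, which are not independent replicates (Pearson's r = 0.765, Spearman's rho = 0.721). At the 3546 TSSs that face a TSS of another gene on the opposite strand within 1000 bp, the medians were 4.94 and 4.84. At the other 17680 TSSs they were 3.86 and 2.37.

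By edgeR's quasi-likelihood interaction test with Benjamini-Hochberg adjustment, 1039 of 21226 TSSs (4.89%) favoured sense and 155 (0.730%) favoured antisense. NOP10, which encodes a small nucleolar ribonucleoprotein, had 50.8 ± 19.4 per sense fragment and 1.76 ± 0.301 per antisense fragment (SD, n = 2 transfections). The histone acetyltransferase gene KAT6B had 52.8 ± 2.03 against 1.68 ± 0.864, RPL8 had 311 ± 158 against 31.7 ± 7.63, and RNVU1-19 had 208 ± 36.3 against 15.1 ± 11.5. SPIRE2, an actin nucleator gene, had 31.5 ± 4.93 against 1.21 ± 1.71, and the sterol isomerase-like gene EBPL had 27.5 ± 15.0 against 2.79 ± 2.26. In the other direction, the antisense RNA gene WDR11-AS1 had 9.33 ± 0.129 per sense and 91.1 ± 31.1 per antisense fragment. At RNH1, which encodes a ribonuclease inhibitor, the values were 15.8 ± 13.5 and 102 ± 38.9. The remaining 4 antisense-biased TSSs each faced a listed gene on the opposite strand. Nearby genes were sought only among the listed TSSs, so WDR11-AS1 and RNH1 may face a gene that is not listed. CNTD1 (0.276 ± 0.391 against 50.2 ± 15.6) faced COA3, a cytochrome oxidase assembly gene, and GMPR2 (4.12 ± 2.17 against 29.6 ± 3.55) faced NEDD8, a ubiquitin-like protein gene. GALNS (15.5 ± 5.23 against 71.7 ± 29.7) faced TRAPPC2L, and RMI1 (10.0 ± 2.12 against 52.7 ± 0.723) faced HNRNPK.

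Antisense bias was called at 103 of the 3546 facing TSSs and at 52 of the other 17680 (Fisher's exact test, odds ratio 10.1, p = 1.63e-43). This test counts every TSS as independent, although TSSs of 1 gene can share fragments, so its p is too small. With 1 TSS per gene, 84 of 11515 favoured antisense. The counts depend on the input and the scaling. All 12 named calls ended when mapped fragments replaced plasmid reads, a setting with a single input column that called only C7orf26 and DNAJC25, both toward sense. Those 2 genes were named after their values were seen. The log2 bias hardly moved at CNTD1, from -7.20 to -7.15 (adjusted p = 0.0742), where both strands had plasmid reads. At the other 11 TSSs the favoured strand had 0 plasmid reads, and the bias shrank, for example from 11.21 to 4.83 at NOP10, from 9.07 to 3.29 at RPL8 and from -8.24 to -2.81 at GMPR2. KAT6B and RMI1 also lost their calls without the top fragment of each TSS (adjusted p = 0.147 and 0.0997), and RMI1 without the filter on low counts (0.0662), with log2 biases that stayed close, at 7.74 against 8.69 for KAT6B and at -6.70 and -7.00 against -7.00 for RMI1. Sense and antisense counts of a library are paired, and with the library as a block 2371 TSSs favoured sense and 354 antisense. TMM and DESeq2 factors moved the median log2 bias from 1.03 to 0.04 and -0.20, and gave 833 sense against 868 antisense and 824 against 1343 TSSs, so the excess of sense calls is relative to equal activity and not to the typical TSS. Without transfection 1 the median log2 bias was 1.08, and without transfection 2 it was 1.06. Each setting left a single cDNA library, with a spread taken from the plasmid PCR replicates alone. Its calls therefore do not account for differences between transfections.

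Because random fragments start and end at different distances from a TSS, active promoters could be read as a deletion series. Fragments reaching 0 to 25 bp upstream of an active TSS kept little activity, 8.43 ± 3.65 (SD, n = 2 transfections), against 62.7 ± 25.5 for fragments reaching 400 to 600 bp. Within each transfection this was 13.1% and 13.6%, a mean of 13.4% ± 0.382. Activity rose steeply over the core promoter, to 23.3 at 50 to 75 bp and 44.5 at 100 to 150 bp, and then slowly, to 80.2 ± 28.3 at 1000 to 1500 bp. On the downstream side short fragments were best. Activity peaked at 135 ± 44.6 for fragments that ended 25 to 50 bp past the TSS and fell to 42.4 ± 18.6 for those ending 1000 to 1500 bp past it, a mean of 30.8% ± 3.58. No test was applied. At the median TSS the shortest upstream class kept 0.615% of activity, and by the share of fragments with any read it kept 38.1%. The median TSS had 19 sense fragments over all lengths, so the first value may reflect classes without a read. Downstream the share of fragments with any read kept 67.4%.

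**Figure D2:**
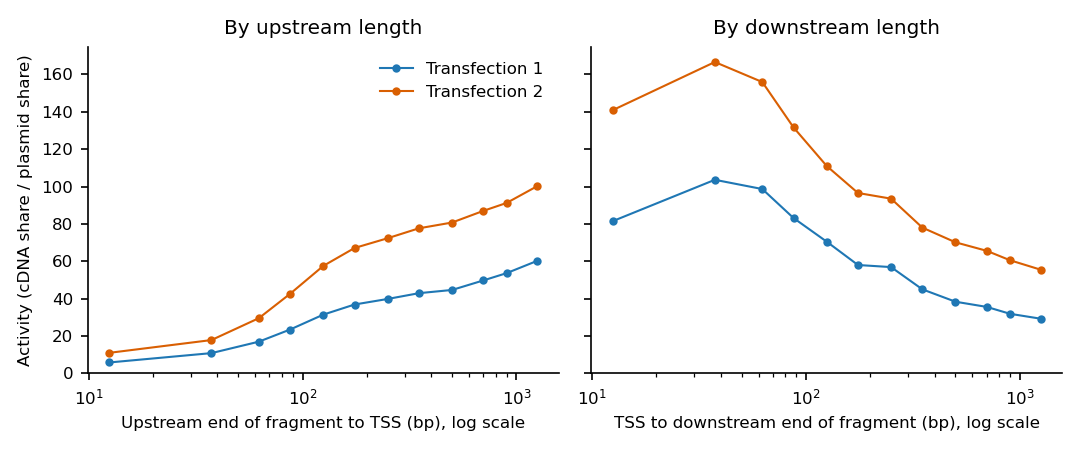
Lines give the activity (cDNA share over plasmid share) of sense fragments containing any of 15309 active TSSs, for each transfection, by the length of the fragment upstream (left) or downstream (right) of the TSS in bp on a log axis, with points at the middle of each length class. Activity rises with upstream length to 60.2 and 100.2, and peaks at 104 and 167 for downstream lengths of 25 to 50 bp.

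Mean activity was concentrated at TSSs. Sense fragments that contained a TSS had an activity of 30.4 ± 11.5 and antisense ones 13.6 ± 4.40 (SD, n = 2 transfections). Fragments centred under 1 kb from a TSS but without it had 3.27 ± 1.02 and 1.84 ± 0.375. From 1 to 5 kb the values were 0.975 ± 0.0211 and 0.901 ± 0.0236, and beyond 100 kb 0.930 ± 0.0521 and 0.914 ± 0.0463. The ratio of TSS-containing sense fragments to those beyond 100 kb was 23.1 in transfection 1 and 43.2 in transfection 2. Counted as the share of fragments with a read, that ratio was 5.74. Fragments with a TSS made up 0.458% of fragments and 5.86% and 9.91% of cDNA reads, while fragments over 1 kb away made up 99.1% of fragments and 93.2% and 88.7% of reads.

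**Figure D3:**
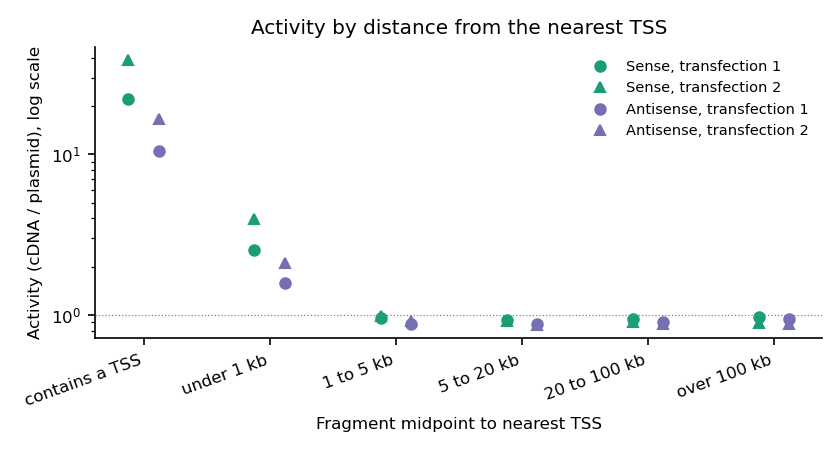
Points give the activity (cDNA share over plasmid share, log axis) of fragments by the distance of their midpoint to the nearest TSS, for each orientation and transfection. TSS-containing sense fragments lie at 22.3 and 38.6, and every class from 1 kb outward lies at or below 0.990.

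The transfections gave similar rankings of TSSs. Across 21848 TSSs, which are not independent replicates, log2 activities of transfections 1 and 2 correlated with Pearson's r = 0.915 and Spearman's rho = 0.949. Both activities were divided by the same pooled plasmid reads, so counting error of this shared input raises the correlation by construction. Per mapped fragment, an input that is also shared, r was 0.905. The level differed, with median activities of 15.4 in transfection 1 and 27.6 in transfection 2. The deposited signal at the TSSs followed activity per fragment with rho = 0.989 and activity over plasmid with rho = 0.956.

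The BAC library, made separately and with shorter fragments, tested 9 of these regions again. SCARNA2, a small Cajal body RNA gene, was its most active named promoter with 86.4 ± 1.55 per fragment (SD, n = 2 untreated transfections), against 176 in the genome-wide library. TAF13, a transcription initiation factor gene, had 49.3 ± 2.54 against 165, NDUFA2 of the respiratory chain had 48.8 ± 1.12 against 61.7, and the tRNA synthetase gene HARS had 44.2 ± 1.86 against 47.2. These 4 were chosen after their values were seen. Activity per fragment is relative to the mean of its own library, over the BAC regions or the whole genome. The paired values are therefore on unlike scales, and their difference does not measure a difference in activity. Of the globin genes in the alpha-globin cluster only HBQ1 and HBM had a listed TSS. HBQ1 had 5.66 ± 0.169 and HBM had 1.66 ± 0.0199. Across 151 TSSs and strands the libraries correlated with r = 0.903 and rho = 0.902. Across 5505 grid points, most of which lie outside promoters, they correlated with r = 0.599 and rho = 0.458. Neither set consists of independent replicates.

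**Figure D4:**
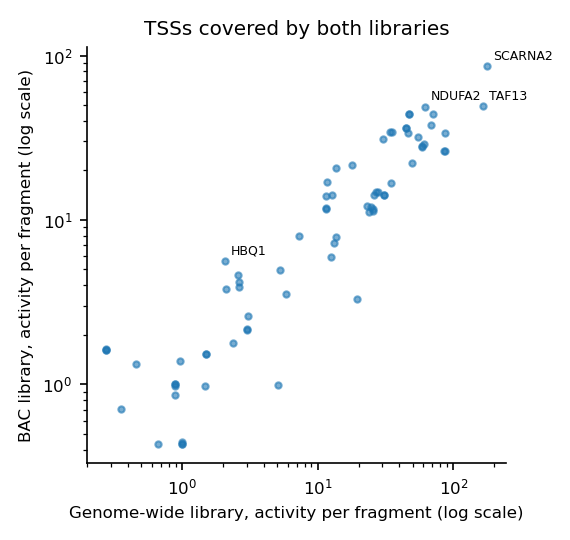
Each point is a TSS, with the activity per fragment of sense fragments in the genome-wide library (x, both transfections pooled, log axis) and in the BAC library (y, mean of 2 untreated transfections, log axis). The 73 TSSs drawn have at least 10 fragments and a cDNA read in both libraries, and SCARNA2 lies at 176 and 86.4.

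The BAC library was also tested under hemin, an iron porphyrin that induces erythroid differentiation of K562, against its solvent. The strongest response lay at the vault RNA gene VTRNA1-1, which RNA polymerase III transcribes in its own setting. Plus-strand fragments over 5:140091000, 140 bp downstream of the VTRNA1-1 TSS, rose 30.7-fold in the TMM-scaled fit. They had 60.2 CPM in solvent and 2268 CPM in hemin (reads scaled to library size without TMM), or 249 and 8338 reads. Folds here and below are TMM-scaled, so they differ from ratios of CPM or reads. At the VTRNA1-1 TSS itself, on the separate scale of TSSs, sense fragments rose 23.6-fold, from 612 to 10089 reads, and antisense fragments rose 11.6-fold. Plus-strand fragments over 5:140092000 and 5:140091500 rose 20.2- and 15.5-fold. Another large rise was at 16:164000, where plus-strand fragments gained 12.3-fold, from 851 to 11368 reads. This point lies 24610 bp downstream of the NPRL3 TSS in the alpha-globin region, and introns of NPRL3 are known to hold distal enhancers of the alpha-globin genes. The 2 PCR replicates of each arm were close at the leading point, with 58.3 and 62.5 CPM in solvent and 2303 and 2231 CPM in hemin.

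The largest falls lay in HOX and globin regions. On chromosome 17, plus-strand fragments over 46599500 fell 4.66-fold, and minus-strand fragments over 46600000 and 46599500 each fell 4.49-fold, all between 8359 and 8859 bp downstream of the TSS of the homeobox gene HOXB1. Plus-strand fragments over 17:46624500, 16141 bp upstream of HOXB1, fell 4.23-fold. All distances in the hemin and solvent comparisons were taken to listed TSSs only. A TSS that is not listed may lie closer to these points. On chromosome 16, minus-strand fragments over 231500 and 232000 each fell 4.36-fold, from 5869 to 1466 and from 2669 to 667 reads, 1048 and 1548 bp beyond the TSS of the theta-globin gene HBQ1.

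**Figure D5:**
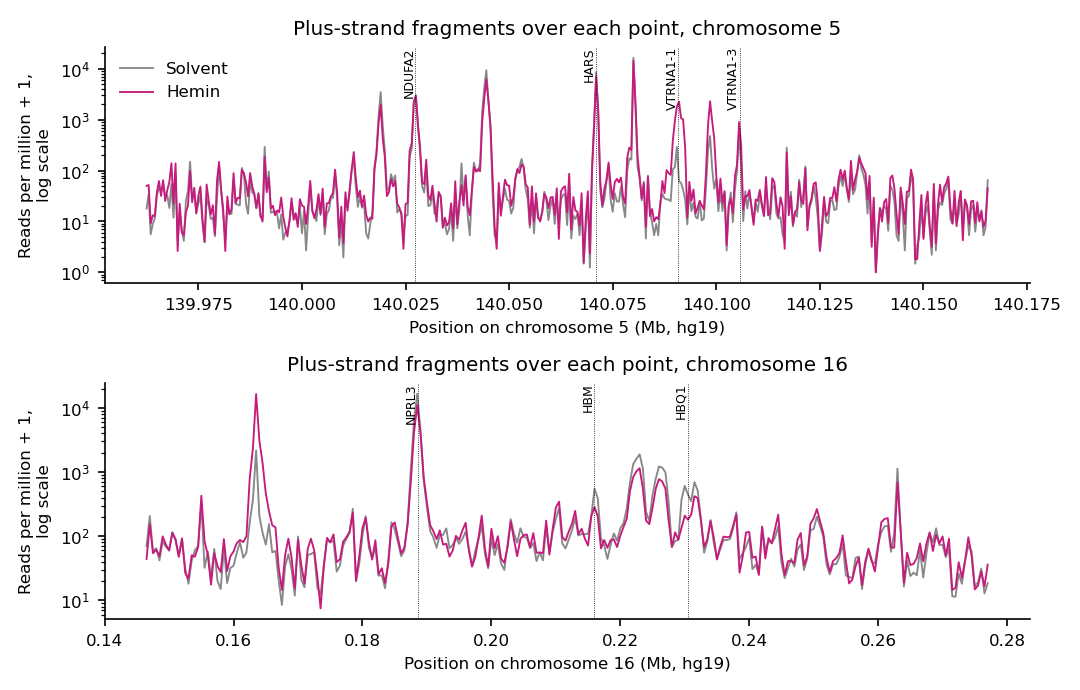
Lines give plus-strand CPM plus 1 (log axis) at points each 500 bp over 2 BAC regions (position in Mb, hg19), with the PCR replicates of each arm summed, and dotted lines mark TSSs. At 5:140091000 the value before adding 1 is 60.2 CPM in solvent and 2268 CPM in hemin, and at 16:164000 it is 206 and 3093 CPM.

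Of 6138 tested grid points, 718 rose and 1043 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 181 and 257 of these changed at least 2-fold. Neighbouring points share fragments and are not independent. Among the regions reported, rises outnumbered falls around ALB (119 against 27), VTRNA1 and HARS (119 against 97), GREB1 (74 against 57) and TAF13 (87 against 77). Falls outnumbered rises around HOXB (223 against 80), HOXD (171 against 84), the alpha-globin genes (118 against 58) and the histone genes (98 against 58). The hemin and solvent arms had 1 transfection each, so the test took its spread from the 2 untreated libraries. Scaling by table totals moved the median of all points from 0.01 to 0.30 on the log2 scale and gave 1975 rises and 560 falls, and DESeq2 gave 48 and 351 with 1735 points given an adjusted p. The changes above are therefore relative to the typical point. Without hemin PCR replicate 1, 451 points rose. PCR replicates as separate libraries gave 366 rises and 852 falls, and with the PCR number as a block the counts were 272 and 768.

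At TSSs, scaled to their own median, 55 of 180 TSS and strand combinations rose and 60 fell with hemin. The 2 globin genes with a listed and tested TSS in the BACs, HBQ1 and HBM, gave fewer reads in the hemin library than in the solvent library. Sense fragments of HBQ1 had 792 and 760 CPM in the untreated libraries, 745 in solvent and 266 in hemin. These CPM lack the TMM factors, while the log2 changes below include them, so the changes are not ratios of the CPM. The log2 change from solvent to hemin was -1.14 (adjusted p = 0.00497 by edgeR's quasi-likelihood test). Sense fragments of HBM, a mu-globin gene, had 658 and 670 CPM untreated, 540 in solvent and 283 in hemin, again without TMM factors. That log2 change was -0.58 (adjusted p = 0.0105), a call that DESeq2 did not make at a change of -0.60 (adjusted p = 0.0769). With 1 transfection per arm, these p values hold only if the arms vary like the untreated libraries. Sense fragments of HARS at 140070917 fell by 0.47. VTRNA1-3, a second vault RNA gene, rose by 1.03. Its 1299 CPM in hemin lay near the 1337 and 1305 CPM of the untreated libraries, and its solvent level was lower, at 810 CPM. HARS and VTRNA1-3 were named after their values were seen. Table totals moved the median of all TSSs from 0.02 to -0.33 and gave 20 rises and 104 falls, and DESeq2 gave 9 and 34.

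The solvent arm was itself compared with untreated cells, as the background of the hemin comparison. Of 6138 points, 278 rose and 172 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 15 and 55 of them changed at least 2-fold. None of the named hemin responses was among the 6 largest solvent changes in either direction. The largest rises had few untreated reads. Minus-strand fragments over 17:46761000 went from 1 read over both untreated libraries to 56 in solvent, and those over 2:176900000 went from 4 reads to 64, or 4.11-fold. The largest fall, 3.93-fold, was on the minus strand at 1:155156000, 6700 bp past the TSS of the mucin gene MUC1. These points were named after their values were seen. Totals instead of TMM moved the median of all points from 0.04 to -0.23 and gave 87 rises and 465 falls, and DESeq2 gave 118 and 21. Because both comparisons share the solvent library, their log2 changes correlate by construction. The observed correlation across points was -0.215 with a covariance of -0.0641, against -0.341 and -0.0317 in 100 simulations without any real change. Observed changes came from the TMM-scaled fit. Simulated ones were log2 ratios with a pseudocount of 1 read, without TMM and with 1 common spread for all points. These are unlike measures, so their difference cannot show whether the correlation goes beyond the shared library.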

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

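The window counts in this part were chosen only after the data were seen, and the mitochondrial strand pattern was noticed in these data before its explanations were tested.

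Fragments of the mitochondrial chromosome, which no comparison of the study's TSSs uses, gave signal that depended on their strand. Minus-strand fragments had a mean activity over plasmid of 1.45 ± 0.182 (SD, n = 2 transfections) and plus-strand fragments 0.656 ± 0.0172. The minus strand was higher by 1.97- and 2.44-fold in transfections 1 and 2 and in all 17 bins of 1 kb in both. Of 170419 windows of 16 kb on the nuclear chromosomes, 4.39% had as large a ratio in both transfections, taken in either direction in each. These windows held far fewer fragments than the mitochondrial plus and minus strands (265740 and 287486), so their ratios vary more by counting. The share therefore cannot place the mitochondrial contrast within the nuclear range. Fewer plasmid reads on the minus strand are argued against as the whole cause, because plus-strand fragments had only 1.06 times as many plasmid reads per fragment. A few outlying fragments are argued against by the share of fragments with a cDNA read, which was 1.51 and 1.40 times higher on the minus strand. What else sets the strands apart stays open, and no biological explanation was tested.

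Signal also appeared far from the listed TSSs. Distances were taken to the 28844 listed TSSs only, so a window may hold a TSS that is not listed. Of 5003921 windows of 1 kb per strand that lie over 5 kb from a TSS, 2234 (0.0446%) reached the median activity per fragment of active TSSs in both transfections (23.6 and 40.9). With a TSS within 500 bp of the centre, 3042 of 27243 windows (11.2%) did. The windows were picked out because they lie outside the main measurement. The most active was minus-strand 8:53864001 to 53865000, with an activity per fragment of 702 ± 394 (SD, n = 2 transfections) over 39 fragments, 225631 bp from the nearest TSS. The next were plus-strand 5:116641001 to 116642000 with 641 ± 427 and plus-strand 1:59938001 to 59939000 with 622 ± 390. No explanation was tested for them.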

How the results depend on the processing

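The settings with PCR pairs as separate libraries, the library block, mapped fragments for orientation, lists and transfection agreement, the held fragment end, the 2-fold hemin call and the minimum of 100 BAC fragments were chosen only after the data were seen. Of the comparison-level results under alternatives, 58 stayed within their limit and 56 moved. The limit was 1.5 times the count for calls. For the correlations of the BAC with the genome-wide library it was a sampling interval that counts positions as independent. They are not, so even small shifts of these correlations counted as moved. The remaining limits were meant to reflect replicate spread. The 24 promoters named for activity (12 by fold and 12 by activity per fragment) kept direction and call in all 262 checks, the 12 orientation genes kept theirs in 87 and lost the call in 15, and the hemin genes and points kept theirs in 236, gained the call in 5 and lost it in 3. Scaling turned the balance of calls for active TSSs (DESeq2), orientation (TMM and DESeq2), hemin at grid points (totals) and solvent (totals). TMM gave 5555 active and 4775 lower TSSs and DESeq2 gave 4670 and 5989, and the antisense-biased TSSs numbered 868 and 1343. Table totals gave 1975 rises and 560 falls with hemin at grid points, 20 and 104 at TSSs, and 87 and 465 for the solvent. DESeq2 gave 48 and 351, 9 and 34, and 118 and 21. With mapped fragments as input edgeR called 0 lower TSSs (1 at an unadjusted p under 0.05), 2 sense-biased and 0 antisense-biased TSSs (2742 and 296 unadjusted), truncation kept 14.9% upstream and 25.1% downstream, and the transfections correlated with r = 0.905. Without the top fragment 158 TSSs were lower, transfection agreement was 0.941, and the BAC libraries correlated over grid points with 0.637. Without the filter the agreement was 0.911, and with a pseudocount of 5 it was 0.937 and the BAC grid correlation 0.630. At 100 BAC fragments or more the latter was 0.717. The replicate block, which pairs the numbered libraries, gave 15093 active and 30 lower TSSs, and the library block gave 2371 sense-biased and 354 antisense-biased TSSs. The PCR number as a block gave 272 rises and 768 falls at grid points and 58 and 62 at TSSs. PCR pairs as separate libraries gave 35 lower TSSs, and PCR replicates as separate libraries gave 366 rises with hemin. Without facing TSSs 55 were antisense-biased, by construction, since facing TSSs held most of them. The 2-fold call gave 181 rises and 257 falls, and the 1000 bp grid, with 3063 points instead of 6138, gave 353 and 515. Upstream truncation kept 0.615% at the median TSS, 38.1% by fragments with a read and 10.5% with the other end held, and downstream truncation kept 20.8%, 67.4% and 37.3%. The ratio of TSS fragments to distal ones was 5.74 by the share with a read. Leaving out 1 replicate gave 611 to 1067 lower, 3308 to 3667 sense-biased and 593 to 1014 antisense-biased TSSs and 451 to 929 rises with hemin. Except where stated, the cause was not tested. Of 23 gene lists, 10 differed from other genes in the main setting and 10 to 13 under the alternatives, the added ones being HOX, muscle and neuronal or small nuclear RNA genes. Depth was low in the genome-wide tests, with a median of 4 plasmid reads per TSS, and its effect on the calls was not tested. Leaving out an untreated BAC library leaves no residual degrees of freedom, so this gave no test. The minimum of 100 plasmid reads for the BAC library was not run, because its plasmid columns were not used, nor were the alternatives for endogenous transcription.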

Other observations

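The comparison of fragments shared within and between PCR pairs, the classes by symbol, the regions of high and low density and the spread per class of level were chosen only after the result was seen.

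Classes of genes grouped by their symbols differed in their share of active promoters. Among genes with RP11 to RP13 clone names, 259 of 550 (47.1%) were active (Fisher's exact test against all other genes, adjusted p = 7.21e-17), with a median activity per fragment of 3.69. LINC symbols reached 49 of 98 (adjusted p = 0.00659) and antisense (-AS) symbols 105 of 195 (adjusted p = 0.00612). Among host genes of small nucleolar RNAs, 7 of 7 were active, with a median of 27.1 (exact adjusted p = 0.0702). MicroRNA symbols had 11 of 16 active (adjusted p = 0.800).

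Fragment density varied along the genome. Against a median of 52455 fragments per Mb, 21 to 26 Mb of chromosome 9 had 0.0241 times and 29 to 31 Mb 0.0197 times as many. The TSS of CDKN2A, a cell cycle inhibitor gene there, had 2 fragments over both strands, and that of MTAP had 0. The largest excesses were 16.1 times the median at 42 to 43 Mb of chromosome 10, 7.55 times at 46 to 47 Mb of chromosome 16 and 5.67 times at 49 to 50 Mb of chromosome 4, followed by 4.65 times at 21 to 24 Mb of chromosome 22. Copy number was not set apart from mapping or repeats. The promoters of CDKN2A and MTAP were not testable with so few fragments.

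PCR replicates of transfection 1 fell into pairs. Replicates of the same pair (1 with 2, 3 with 4) shared 50.2% of the fragments of the smaller library, and replicates of different pairs shared 9.93%. Low depth alone is argued against, since replicates 3 and 4, which had the fewest reads, still shared 49.2%. Separate pools of molecules are a candidate explanation, because a library of transfection 2 thinned to the same number of fragments shared 10.7%, about as many as between pairs. No biological explanation was tested.

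With hemin, promoters fell against their surroundings in the BAC library. On table totals the median log2 change was -0.32 for sense TSSs and 0.27 for grid points, a gap of 0.59. Only positions with at least 50 solvent reads entered here, whereas the 0.30 given above covers all tested points. Uneven amplification in hemin PCR replicate 1 is argued against as the whole cause, because the gap was 0.54 with hemin PCR replicate 2 alone. A uniform background added to the hemin library cannot be told apart from a loss of promoter activity. The change fell with the untreated level (rho = -0.50 across grid points; medians 0.51, 0.36, 0.17 and -0.18 from the lowest to the highest of 4 equal classes of level), as such a background may produce, but the points of the highest class did not fall alike, with an interquartile range of 0.73 against 0.44 to 0.54 in the others. An effect of hemin on promoters stays open too, since each arm had 1 transfection.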
